A study of Mus musculus with 12 samples.

How the data were processed

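RNA sequencing was done on neurons of the pontine nucleus, a hindbrain nucleus that relays signals from the cortex to the cerebellum, taken from CD-1 mouse embryos at embryonic day 18.5. Per the labels, the neurons were genetically labelled, microdissected, dissociated and sorted by FACS at 2000 cells per replicate, and RNA was extracted with a PicoPure kit. RNA of 1000 cell equivalents was amplified by SPIA with the Ovation RNA-seq System V2, and 1 ng of cDNA went into TruSeq Nano libraries. The authors deposited 1 table of raw read counts for 23079 genes identified by Entrez number in 12 libraries, with the length of each gene in bases and no normalization. The processing notes name the mouse genome build mm10 and base calling with bcl2fastq version 1.8.4. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here.

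The labels hold 3 groups: Math1tdTomato, called the reference here because the series design says so (n = 6), Hoxa5tdTomato (n = 3), and Math1Hoxa5-IRES-GFP, called the driven group here because its columns name a Cag and lsl Hoxa5 allele (n = 3). The column names split the references into those that name creErt2 and those that name tdT. From the words of the names, the libraries were paired here into 2 sets. No name states which references belong with which other group, and all results within a set rest on this pairing. In set 1 the 3 Hoxa5tdTomato libraries stand with 3 reference libraries whose columns name creErt2. In set 2 the 3 driven libraries stand with 3 reference libraries whose columns name tdT. Total counts ran from 9973484 to 13302076 per library in set 1 and from 22355961 to 29820776 in set 2, so depth and set cannot be told apart. The reference columns carry numbers 1 to 3 within each set and could not be matched to the label numbers 1 to 6; they were used by group, which needs no match. The set was not a term of the planned fit. A fit of 4 groups, with the references of each set apart, was added after the data were seen, and named genes that passed in the pooled fit but not there are given with their adjusted p. Values within a set come from this fit. They compare libraries of 1 set, but scaling and spread were estimated over all libraries. The p values within a set therefore also depend on the libraries of the other set.

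Symbols and positions came from the GRCm38.p6 gene annotation, which matched 23008 of 23079 identifiers (99.7%). Genes were kept with the filterByExpr rule of edgeR at a minimum count of 10, which left 14732 genes. Counts were scaled with TMM factors, and CPM, the edgeR count of a gene relative to the scaled library size, is given as mean ± SD over libraries. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on a design with 1 mean per group, and Benjamini-Hochberg adjusted p values over the 14732 genes were held against 0.05. The common dispersion was 0.312. Fold changes are log2 values from that fit, given ± their standard error; they are positive where the group named first is higher. A fold against a group with a count of 0 was bounded from a floor of 3 counts over the whole group, and with 1 to 3 counts the ratio is given with its 95% exact binomial (Clopper-Pearson) interval. These limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The floor of a single library lay between 0.107 and 0.274 CPM.

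Before the data were examined, 3 comparisons, 40 gene lists and the rule for naming genes were fixed. The comparisons were Hoxa5tdTomato against the reference, driven against the reference, and Hoxa5tdTomato against driven; the genes changed in the same direction in both comparisons with the reference were counted as a further result. The lists covered Hox genes of low and high paralog groups, their TALE cofactors, transcription factors of the precerebellar rhombic lip lineage, the Netrin and Slit system, Eph receptors and ephrins, semaphorins with plexins and neuropilins, cadherins, protocadherins, contactins and related adhesion molecules, and synaptic organizers. Further lists covered glutamate receptors, GABA and glycine receptors, potassium channels, retinoic acid, Polycomb and Wnt genes, immature and maturing neuron genes, and neuropeptides. The lists of other cell types held markers of GABAergic, serotonergic, noradrenergic, cholinergic and cerebellar granule neurons, astrocytes, oligodendrocytes, microglia, endothelium, pericytes, meninges, erythroid cells, ependyma and dividing cells. The lists for RNA quality held stress, hypoxia, mitochondrially encoded, ribosomal protein, histone and sex-linked genes. Each list with at least 3 tested genes (37 lists) was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry.

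Named genes were chosen by rule. Hoxa5 came first, then the 10 largest changes in each direction among genes past the threshold whose libraries did not overlap between the groups and whose mean reached 5 CPM in the higher group, with predicted genes and pseudogenes left out. Up to 4 members of each list past the threshold by smallest p followed, or at most 2 by highest mean where none passed. Unc5b and Unc5c, netrin receptors, are always given. For the third comparison the 5 largest in each direction were taken, and for the genes changed in both up to 10 by the larger adjusted p. After the data were seen, the 10 first by the same order in the fit within the sets were added. Some genes chosen by these rules are not given by name.

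The fit was tested on simulated data in 5 runs with 200 changed genes each. It recovered 19.2% of genes changed 2-fold and 58.2% of genes changed 4-fold in the first comparison, and 19.0% and 55.2% in the second; within the sets it recovered 11.4% and 50.4%, and 13.2% and 49.2%. False genes made up 4.61% to 6.18% of the calls. The simulated libraries held no difference between the sets and no outlying library, so this share does not cover either in the real data. In these simulations, changes of 2-fold were missed more often than found.

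The alternatives tried were other scaling factors (RLE, upper quartile, library size alone), no filter and a stricter filter at 50 counts, DESeq2 1.42.0, limma voom with quality weights, a robust fit, only the groups compared, a threshold of 0.01, a minimum fold of 1.5, and leaving out each of the 12 libraries. A planned block by the replicate numbers of the labels was not run, since the reference columns do not carry those numbers. Alternatives added after the data were seen were a block by the numbers in the columns, counts thinned to the shallowest library, and the fit within the sets. The last was run alone, without driven replicate 3, with a block, and on thinned counts. All columns of per-sample values were used.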

Results

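Gene expression was measured by RNA sequencing in sorted pontine nucleus neurons of mouse embryos shortly before birth, in 12 libraries of 3 groups. The reference group, Math1tdTomato (n = 6), was labelled through Math1 (Atoh1), a transcription factor gene of the rhombic lip, from which pontine neurons arise. Hoxa5tdTomato (n = 3) was labelled through Hoxa5, a homeobox gene that patterns the hindbrain and spinal cord along the body axis. In Math1Hoxa5-IRES-GFP (n = 3), the driven group, the labels name a Hoxa5 allele meant to be driven in the Math1 lineage. The Hoxa5tdTomato libraries and 3 references made up set 1, with 9973484 to 13302076 counts per library. The driven libraries and the other 3 references made up set 2, with 22355961 to 29820776. Between 13074 and 16290 genes had a count in a library. Driven replicate 3 had the lowest number. Across genes its log2 CPM correlated with that of the other driven libraries at a lowest r of 0.860, against 0.926 to 0.943 among the replicates of the other groups and sets. The embryos were of both sexes, with Xist, the RNA of the inactive X chromosome, at 4.36 to 10.9 CPM in Hoxa5tdTomato replicate 1, set 2 reference replicate 2 and driven replicate 3, and at 1570.1 to 5440.4 CPM in the other libraries. Mitochondrially encoded genes were not among the genes of the table.

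The first comparison asked how pontine neurons labelled through Hoxa5 differ from the general Math1 population. Hoxa5 itself stood at 156 ± 57.0 CPM in Hoxa5tdTomato (SD, n = 3) and 14.2 ± 10.9 CPM in the references (SD, n = 6), a log2 fold change of 3.46 ± 0.59, adjusted p = 0.00712. All 3 libraries (119 to 222 CPM) lay above all 6 references (4.35 to 32.2 CPM), and an exact two-sided permutation test over 84 splits gave p = 0.0119, the smallest value it can give, or 0.0238 adjusted over both comparisons with the reference. Those splits ignore the set, and set 1 holds too few libraries for such a test to reach 0.05. Other Hox genes of nearby paralog groups rose as well: Hoxa4 was at 2.76 ± 0.44, adjusted p = 0.00416, Hoxc4 at 2.28 ± 0.29, adjusted p = 0.00103, and Hoxb5 at 1.60 ± 0.32, adjusted p = 0.0171, each higher in 3 of 3 libraries than in any reference. Hoxa7 was at 4.07 ± 1.40 CPM and had no count in any reference, so that it was at least 145-fold higher. Of the Hox genes of paralog groups 5 to 13, 3 of 4 tested genes rose and 0 fell, and 4 rose adjusted over the list alone. The median was 2.72, also with Hoxa7 at its floor, with a camera adjusted p = 2.70e-07, and 0.0144 with an estimated correlation. Hoxa5, through which these neurons were labelled, is in this list, which was not tested without it. Of its 27 members 4 were tested. Hoxa7 had no count in any reference or driven library, so it passed the filter only through Hoxa5tdTomato, where it was high. Of paralog groups 1 to 4, 2 of 10 tested genes rose and 0 fell, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0924). Within set 1, in the fit of 4 groups, the changes were 2.47 for Hoxc4 (adjusted p = 0.00424), 2.89 for Hoxa4 (0.0359) and 1.94 for Hoxb5 (0.0273). Hoxa5 was at 3.53 there, and its adjusted p of 0.0698 missed the threshold. Without Hoxa5tdTomato replicate 2, Hoxa5 stood at 3.11 with an adjusted p of 0.0693. Within set 1 camera called the list of paralog groups 1 to 4 (adjusted p = 0.00383, or 0.209 with an estimated correlation). In other fits within set 1 Hoxa5 passed, at adjusted p values of 0.00279 without driven replicate 3, 0.00467 with a block and 0.0499 on thinned counts. Hoxa7 did not pass within set 1 (adjusted p = 0.151).

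**Figure D1:**
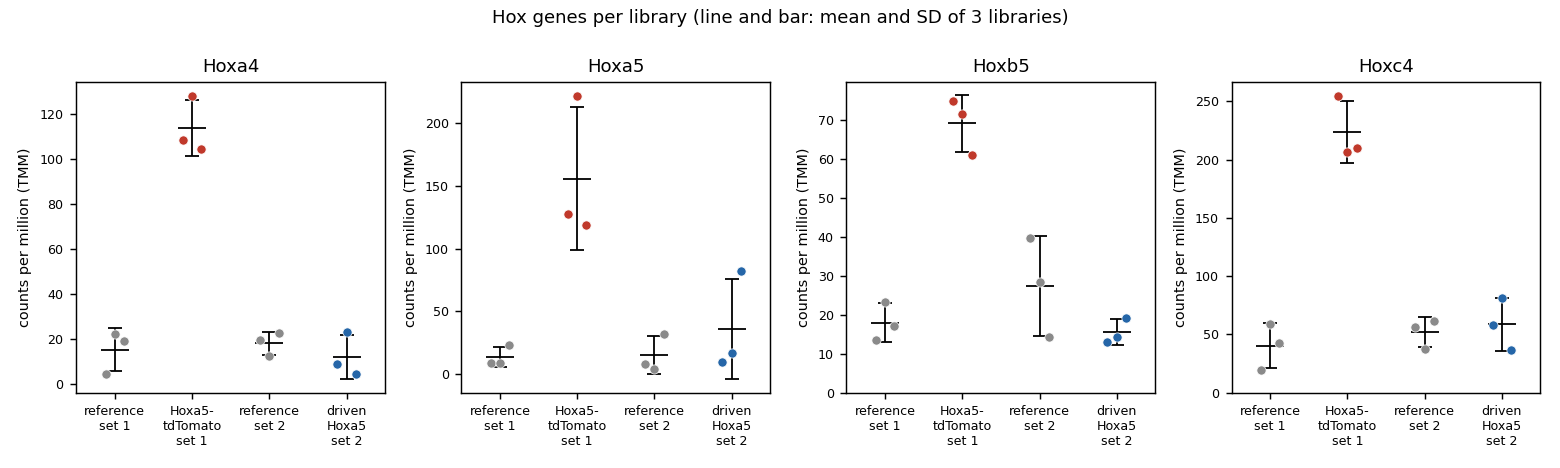
TMM-scaled CPM of Hoxa4, Hoxa5, Hoxb5 and Hoxc4 in each library, one point per library, in the references and Hoxa5tdTomato of set 1 and the references and driven group of set 2; lines and bars give the mean and SD of 3 libraries. In Hoxa5tdTomato all 3 points lie above every reference, while in the driven group Hoxa5 is at 9.73, 16.8 and 82.0 CPM and overlaps the references.

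Some transcription factors of the rhombic lip lineage were lower in Hoxa5tdTomato. In that list 0 of 19 tested genes rose and 4 fell, with 0 higher and 7 lower adjusted over the list alone. The median was -0.72 with a camera adjusted p = 1.61e-05, or 0.264 with an estimated correlation. Nfib, Nfix and Nfia, nuclear factor I genes that act in neuronal differentiation, fell by 0.83 ± 0.14, 1.25 ± 0.23 and 1.12 ± 0.21 on the log2 scale; Nfib stood at 3095 ± 338 against 5502 ± 599.9 CPM (SD, n = 3 and 6). Nhlh1, a basic helix-loop-helix gene of young neurons, was at -2.96 ± 0.64, adjusted p = 0.0266. The median of the list in the set 1 references against the set 2 references was -0.51 (camera adjusted p = 0.00393, or 0.663 with an estimated correlation). Its median in Hoxa5tdTomato within set 1 was -0.53 (camera adjusted p = 0.00116, or 0.315 with an estimated correlation). Among the immature neuron and migration genes, 1 of 21 tested genes rose and 3 fell, with 3 higher and 6 lower adjusted over the list alone and a camera adjusted p of 0.0909. The median of -0.10 turned to 0.06 with library size as the only scaling. Reln, the secreted positioning signal Reelin, was higher at 1.12 ± 0.16, adjusted p = 0.00184, while Sox11 (-0.93), Igfbpl1 (-1.03) and Sox4 (-0.79) were lower, with adjusted p values of 0.0104, 0.0196 and 0.0352. None of the 11 TALE cofactors passed over all genes, and 3 were lower adjusted over the list alone. Meis1 was at -0.31 (adjusted p = 0.477), with a camera adjusted p of 0.0909. Camera called the immature neuron list within set 1 (adjusted p = 0.0194, or 0.143 with an estimated correlation). Within set 1 Nhlh1 was at -1.73 and did not pass (adjusted p = 0.172), nor did Nfia (0.0658), Igfbpl1 (0.125) and Sox4 (0.151). Nfix was at -0.82 there and passed (adjusted p = 0.0359).

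Axon guidance receptors changed in both directions. Nrp1, a neuropilin that binds semaphorins, was at 364 ± 57.3 against 832 ± 83.5 CPM, a change of -1.19 ± 0.15, adjusted p = 0.00103, while the related Nrp2 was at 167 ± 44.5 against 64.6 ± 22.4 CPM (1.37 ± 0.24, adjusted p = 0.00756). Plxnd1, a semaphorin receptor that is also expressed by blood vessels, was higher (1.92 ± 0.28, adjusted p = 0.00212) and Sema6d lower (-0.88 ± 0.17, adjusted p = 0.0141). In the list of semaphorins, plexins and neuropilins, 3 of 30 tested genes rose and 4 fell, with 3 higher and 5 lower adjusted over the list alone and a camera adjusted p of 0.333. In the Netrin and Slit list 1 of 22 tested genes rose and 2 fell, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.507). Slit3 was at 2.23 ± 0.52, Robo3 at -2.15 ± 0.51 and Dcc, a netrin receptor, at -1.75 ± 0.43. None of these 3 passed within set 1, where they stood at 2.21, -1.34 and -1.23 with adjusted p values of 0.226, 0.287 and 0.318. The netrin receptor genes Unc5b (1.24 ± 0.68, adjusted p = 0.434) and Unc5c (-0.17 ± 0.27, adjusted p = 0.849) did not pass. Of the Eph receptors and ephrins, 0 of 21 tested genes rose and 2 fell, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.133). Ephb1 was at -1.11 ± 0.20 and Epha3 at -1.53 ± 0.32. Epha3 did not pass within set 1 (adjusted p = 0.0940).

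Some adhesion molecules changed. Ncam2, a neural cell adhesion molecule, was at 67.1 ± 18.0 against 268 ± 43.3 CPM, a change of -2.00 ± 0.22, adjusted p = 0.000432. Cadm2 (1.799 ± 0.23, adjusted p = 0.00103) and Negr1 (1.09 ± 0.14, adjusted p = 0.00103), adhesion molecules of the immunoglobulin family, were higher. Cntn2 was lower (-1.41 ± 0.27, adjusted p = 0.0141). In the list of contactins and related molecules, 5 of 35 tested genes rose and 3 fell, with 7 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.197). Of the classical cadherins, 0 of 16 tested genes rose and 1 fell, 1 adjusted over the list alone (Cdh2, -0.75 ± 0.15; camera adjusted p = 0.477). Of the protocadherins, 1 of 11 tested genes rose and 0 fell, 3 adjusted over the list alone (Pcdh19, 1.64 ± 0.36), with a camera adjusted p of 0.0410, or an adjusted p of 0.332 with an estimated correlation. Of the synaptic organizers, 3 of 40 tested genes rose and 2 fell, with 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.477). The teneurins Tenm1 (1.25 ± 0.17, adjusted p = 0.00173) and Tenm3 (1.01 ± 0.24) and Flrt2 (0.73 ± 0.17) were higher and C1ql3 was lower (-2.15 ± 0.49). Within set 1 the changes of Cntn2 (0.0940), Cdh2 (0.0940), Pcdh19 (0.210), Flrt2 (0.136) and C1ql3 (0.256) did not pass (adjusted p in brackets), with C1ql3 at -1.29.

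**Figure D2:**
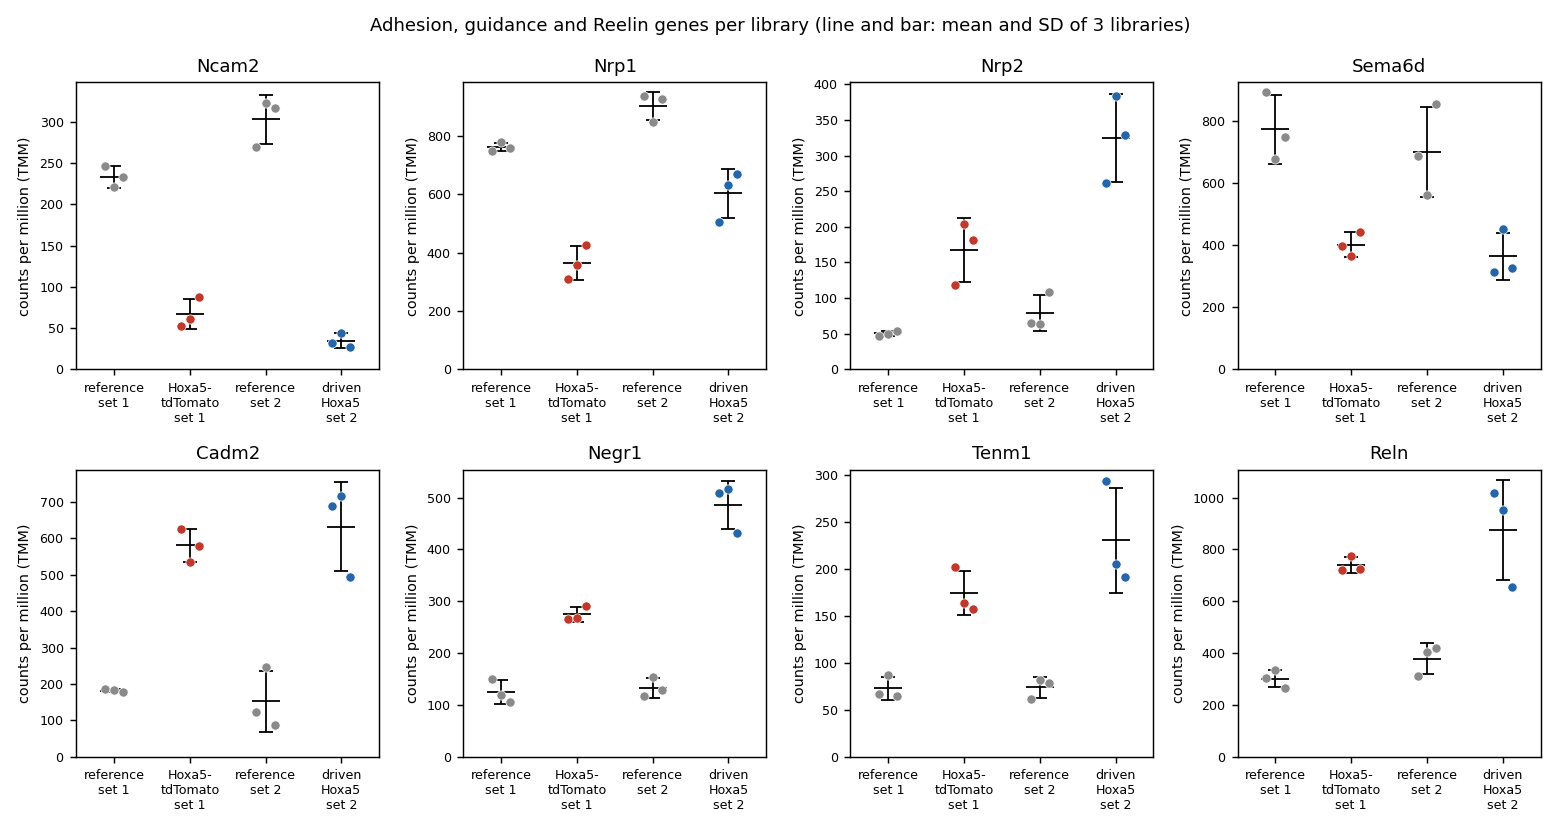
TMM-scaled CPM (axes from 0) of 8 adhesion, guidance and Reelin genes in each library, one point per library; lines and bars give the mean and SD of the 3 libraries of a group in its set. In both comparisons Ncam2 and Sema6d lie below the references of their set, and Nrp2, Cadm2, Negr1, Tenm1 and Reln above them.

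Genes of synaptic transmission were higher in part. Grm5, a glutamate receptor gene, was at 1.43 ± 0.33, adjusted p = 0.0367, Gabrb2, a GABA receptor subunit gene, at 1.44 ± 0.22, adjusted p = 0.00316, Syt4, a synaptotagmin gene, at 1.43 ± 0.26, adjusted p = 0.0104, and Kcnd2, a potassium channel gene, at 1.02 ± 0.19, adjusted p = 0.0112. Kcna2, another potassium channel gene, was lower (-1.29 ± 0.27, adjusted p = 0.0226), as was Sst, which encodes somatostatin (-1.68 ± 0.39, adjusted p = 0.0366). In the glutamate list 1 of 28 tested genes rose and 0 fell, with 5 higher and 1 lower adjusted over the list alone. Its camera adjusted p was 0.0248, or 0.370 with an estimated correlation. In the GABA and glycine receptor list 1 of 18 tested genes rose and 0 fell, with 5 higher and 0 lower adjusted over the list alone. The camera adjusted p was 0.0123, or 0.332 with an estimated correlation. The counts adjusted over the list alone were 3 higher and 1 lower of 30 potassium channels (camera adjusted p = 0.132), 3 higher and 2 lower of 27 maturing neuron genes (0.0635), 0 higher and 1 lower of 13 neuropeptides (0.371) and 2 higher and 3 lower of 33 Wnt genes (0.0924). Among the last, Sfrp4, a secreted Wnt modulator, was at 2.01 ± 0.32, adjusted p = 0.00453. No gene passed over all genes in the retinoic acid list, with 0 higher and 2 lower adjusted over the list alone (Crabp1 -1.72, Cyp26b1 -0.18, camera adjusted p = 0.602). None passed either way in the Polycomb list (Phc3 -0.38, Phc1 -0.60). The Polycomb list as a whole was lower, with a median of -0.25 and a camera adjusted p of 0.0442, or 0.264 with an estimated correlation. Within set 1 its camera adjusted p was 0.147. Within set 1 camera called the maturing neuron (0.000162) and Wnt lists (0.0336), neither with an estimated correlation (0.143 each). Within set 1 the changes of Grm5 (0.280), Syt4 (0.0828), Kcna2 (0.130), Sst (0.172) and Sfrp4 (0.0526) did not pass (adjusted p in brackets).

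Several genes of blood vessels were among the largest increases in the same Hoxa5tdTomato libraries. The increases are listed by size and not by cell type, and Ptger3 rose in the driven group too (3.63 ± 0.78, adjusted p = 0.0200). Anpep, an aminopeptidase gene of pericytes, had no count in any reference and was at 6.00 ± 6.38 CPM, at least 214-fold higher. Apln (7.98 ± 1.45) and Aplnr (5.17 ± 1.23), which encode apelin and its receptor, Cmklr1 (7.10 ± 1.32), Dock6 (5.41 ± 1.11), Esam (4.42 ± 1.09), Abcc9 (4.31 ± 1.00), Itga4 (4.15 ± 1.01), Ptger3 (4.10 ± 0.79) and Col4a1 (3.91 ± 0.87) followed, each higher in 3 of 3 libraries than in any reference. Of 14 endothelial markers 1 rose over all genes and 12 adjusted over the list alone, with a median of 3.32. The counts were, of 10 pericyte markers 2 and 7 (median 3.22), and of 8 meningeal markers 0 and 4 (median 2.95). Their camera adjusted p values were 3.30e-13, 3.77e-07 and 0.000890, or 0.150 each with an estimated correlation. With fry the adjusted p values were 0.00732, 0.00732 and 0.00621. Within set 1 the medians were 3.36, 3.35 and 2.82. The vascular genes were low: Abcc9 stood at 58.0 ± 27.9 CPM and Rgs5, a pericyte marker, at 26.9 ± 11.1 CPM, against 2.97 ± 3.5 and 2.37 ± 1.21 CPM in the references. The largest decreases were Drd5 (-6.06 ± 1.36), Esr1 (-4.61 ± 0.94), Sstr2 (-3.36 ± 0.83), Nhlh1, Bcl2l11 (-2.30 ± 0.48), Fbxl7 (-2.24 ± 0.45), Stk10 (-2.24 ± 0.47), Robo3, C1ql3 and Rcor2 (-2.13 ± 0.53). Drd5 and Sstr2 encode receptors for dopamine and somatostatin, and Esr1 encodes an estrogen receptor. Within set 1 Aplnr (0.0458) passed, but the increases of Anpep (0.282), Apln (0.148), Cmklr1 (0.116), Dock6 (0.106), Esam (0.323), Abcc9 (0.314), Itga4 (0.267), Ptger3 (0.157), Col4a1 (0.268) and Rgs5 (0.261) did not (adjusted p in brackets). Of the decreases Esr1 (0.0433) passed there, and Drd5 (0.0774), Sstr2 (0.253), Nhlh1 (0.172), Bcl2l11 (0.153), Fbxl7 (0.116), Stk10 (0.0575), Robo3 (0.287), C1ql3 (0.256) and Rcor2 (0.272) did not.

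**Figure D3:**
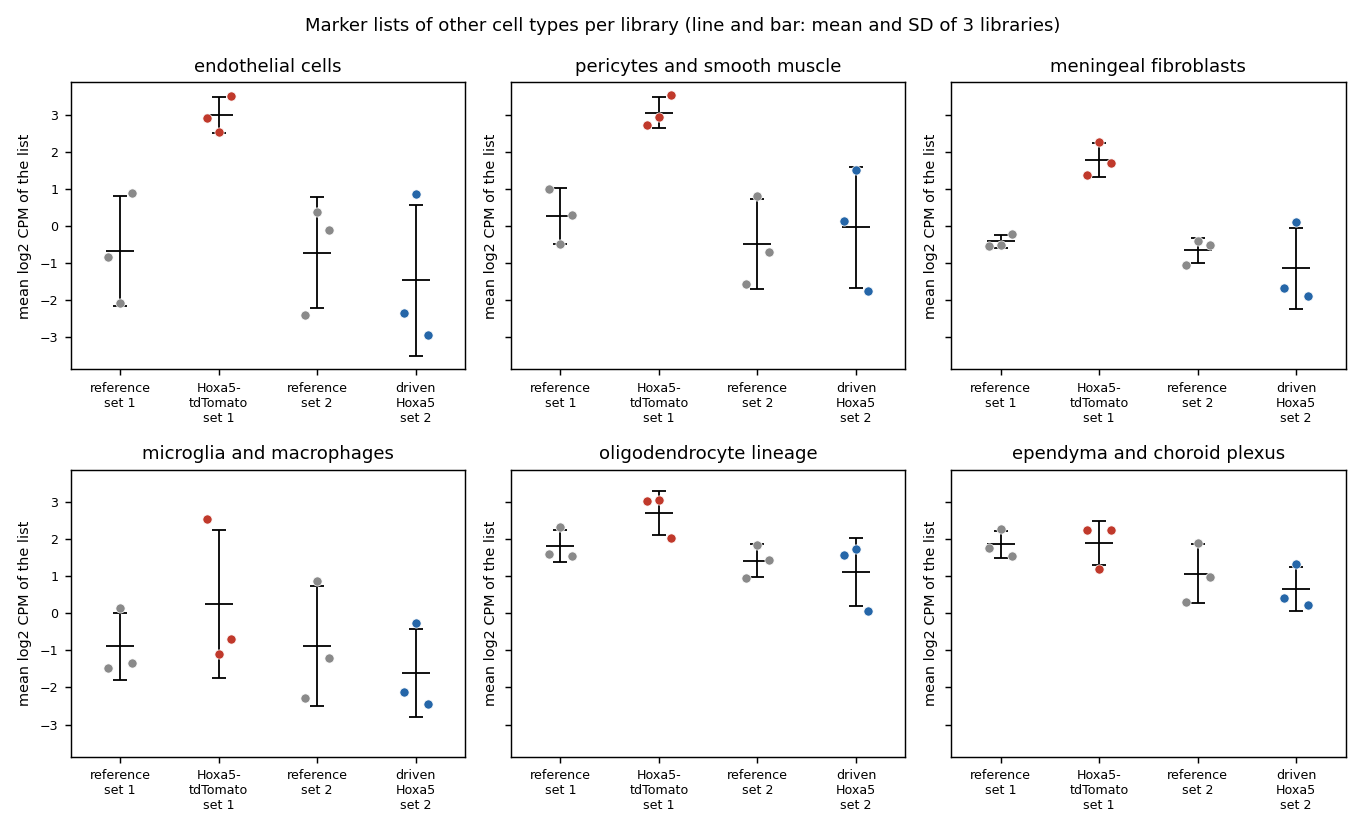
Mean log2 CPM of the tested members of 6 marker lists in each library, one point per library; lines and bars give the mean and SD of 3 libraries. The endothelial, pericyte and meningeal lists lie higher in all 3 Hoxa5tdTomato libraries than in any other, while microglial markers lie high in Hoxa5tdTomato replicate 1 alone of its group.

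Markers of other cell types and of RNA quality were measured in the same way. Of the astrocyte and radial glia markers, 2 of 15 tested genes rose and 0 fell (Ptprz1 1.58, Slc4a4 1.38), 2 adjusted over the list alone, with a camera adjusted p of 0.0297, or 0.284 with an estimated correlation. The oligodendrocyte list had a median of 0.63 (camera adjusted p = 0.0123), or an adjusted p of 0.264 with an estimated correlation, with 0 of 12 genes past the threshold either way. The medians of lists that camera did not call were 0.84 (camera adjusted p = 0.104) for GABAergic and glycinergic neurons, with 3 higher and 1 lower adjusted over the list alone, -0.07 (camera adjusted p = 0.804) for serotonergic, 0.12 (camera adjusted p = 0.602) for cholinergic and -0.08 (camera adjusted p = 0.129) for cerebellar granule neurons, where Cntn2 was lower. They were 1.88 (camera adjusted p = 0.0924) for microglia, 0.08 (camera adjusted p = 0.476) for ependyma and 0.43 (camera adjusted p = 0.159) for dividing cells, with 1 gene higher adjusted over the list alone. The serotonergic and granule neuron medians turned to 0.09 each with library size as the only scaling. Too few genes were tested for camera in the noradrenergic list (Th -2.71, adjusted p = 0.0995; Tfap2b 0.63, 0.916) and the erythroid list (Alas2 0.69, 0.772; Hbb-bs 2.45, 0.565). Of the stress genes, 1 rose (Klf6, 1.08) and 1 fell (Ier5, -1.08), also adjusted over the list alone, with a median of 0.59 and a camera adjusted p of 0.0357, or 0.264 with an estimated correlation. Of the hypoxia genes, 1 rose, 3 adjusted over the list alone, with 0.0248, or 0.332 with an estimated correlation. The gene was Slc2a1 (3.07 ± 0.44, adjusted p = 0.00184), the glucose transporter of brain endothelium. The ribosomal protein list was higher (median 0.41, camera adjusted p = 5.60e-10, or 0.305 with an estimated correlation), and within set 1 its median was 0.11 (0.114). Histone and sex-linked genes had medians of 0.08 (camera adjusted p = 0.507) and 0.23 (camera adjusted p = 0.430). The GABAergic list was called within set 1 (camera adjusted p = 0.0211, or 0.143 with an estimated correlation). Within set 1 the changes of Ptprz1 (0.0540) and Slc4a4 (0.107) did not pass (adjusted p in brackets), and the astrocyte list was not called (camera adjusted p = 0.0583).

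In all, 255 of 14732 genes passed in this comparison, 124 higher and 131 lower, and 14 of 37 lists were called, of which the Hox genes of paralog groups 5 to 13 alone held with an estimated correlation. That list holds Hoxa5, the gene that labelled the group, so its call is in part given by the labelling. It is also in part given by the filter, which left 4 of 27 members and which Hoxa7 passed only through Hoxa5tdTomato. With library size as the only scaling 170 rose and 70 fell. Within set 1, 82 genes passed (43 higher, 39 lower), 71 of them among the 255, and all 255 kept their sign. Of the 255, 7 also differed between the references of the sets. The count was 36, 35 and 52 without Hoxa5tdTomato replicates 1, 2 and 3, 141 and 121 without set 2 reference replicates 1 and 3, and 728 without driven replicate 3. Of 69 named genes past the threshold, 19 stayed past it in every fit that left out 1 library: Aff2, Brinp3, Cadm2, Fat4, Gabrb2, Hoxa4, Hoxc4, Lmo3, Ncam2, Negr1, Nrp1, Plxnd1, Reln, Rnf152, Sfrp4, Slc2a1, Spock1, Tenm1 and Wscd1. Without Hoxa5tdTomato replicates 1, 2 and 3, 47, 47 and 43 of the 69 no longer passed, without a reference 13 to 26, and without a driven library 0 to 2. The number of lists was 8 without set 1 reference replicate 1 and 8 without Hoxa5tdTomato replicate 1.

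The second comparison set the driven group against the reference. Hoxa5 itself did not pass in it. The largest changes in the driven libraries included Calb1 and Kcnj2, which were higher, and Lhx2, which was lower. Calb1 (2.02 ± 0.43, adjusted p = 0.0241), Kcnj2 (2.37 ± 0.44, 0.0113) and Syce2 (2.00 ± 0.45, 0.0309) also passed as higher in Hoxa5tdTomato, though not within set 1. Calb1, which encodes the calcium-binding protein calbindin, was at 99.0 ± 37.5 against 10.03 ± 6.87 CPM (SD, n = 3 and 6), a change of 3.30 ± 0.43, adjusted p = 0.000490. Kcnj2, an inward rectifier potassium channel gene, was at 40.0 ± 10.6 against 3.23 ± 1.59 CPM (3.63 ± 0.44, adjusted p = 0.000212). Lhx2, a LIM homeobox gene, fell from 33.5 ± 24.2 to 0.923 ± 1.30 CPM (-5.16 ± 0.94, adjusted p = 0.00732), and Ncam2 from 268 ± 43.3 to 34.6 ± 8.89 CPM (-2.95 ± 0.23, adjusted p = 1.45e-06). Hoxa5 itself stood at 36.2 ± 39.8 CPM (9.73, 16.8 and 82.0), with a change of 1.35 ± 0.59, adjusted p = 0.255. The exact two-sided permutation p was 0.167 over 84 splits, and driven replicate 3 alone lay above all references. Without driven replicate 3 the Hoxa5 change was -0.10. None of 4 Hox genes of groups 5 to 13 passed (median -0.18; Hoxb5 -0.56), and none of 10 of groups 1 to 4 (median 0.07; Hoxa2 0.26, Hoxb3 0.34), where 1 was higher adjusted over the list alone. Their camera adjusted p values were 0.988 and 0.915. The median of groups 1 to 4 turned to -0.06 with library size as the only scaling.

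The other largest increases were Npnt (4.38 ± 0.78, adjusted p = 0.00589), Ptger3 (3.63 ± 0.78), Cpne2 (3.46 ± 0.55), Tll1 (3.33 ± 0.47), Tmem159 (3.23 ± 0.61), Prkcd (2.89 ± 0.57), Galr1 (2.84 ± 0.51), a galanin receptor gene, and Syce2 (2.79 ± 0.45), each higher in 3 of 3 libraries than in any reference. The other largest decreases were Ren2, with 2 counts in the driven group and a ratio of 283 (95% interval 78.2 to 2344), St3gal1, a sialyltransferase gene (-5.11 ± 0.61, adjusted p = 0.000185), Fam64a (-4.21 ± 0.89), Glis1 (-3.49 ± 0.68), Gprc5c (-3.40 ± 0.79), Phex (-3.16 ± 0.60), Tmem132c (-3.07 ± 0.70) and Wnt5a, a secreted Wnt ligand (-3.07 ± 0.63, adjusted p = 0.0144). Within set 2, Calb1 was at 3.08 (adjusted p = 0.0131), Kcnj2 at 3.73 (0.00524), Lhx2 at -5.75 (0.00524), St3gal1 at -5.12 (0.000956) and Npnt at 4.26 (0.0761). In the rhombic lip list Lhx2 was the 1 gene of 19 past the threshold, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.659), and of 11 TALE cofactors none passed either way (camera adjusted p = 0.942). Of the Wnt genes, 1 of 33 tested genes rose and 1 fell (Sfrp4 2.41 ± 0.32, adjusted p = 0.000546; Wnt5a), with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.915). The changes of Ptger3 (0.109), Tmem159 (0.0949), Glis1 (0.0595) and Tmem132c (0.0885) did not pass within set 2 (adjusted p in brackets).

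Guidance and adhesion genes changed here too. Nrp2 was at 324 ± 61.6 against 64.6 ± 22.4 CPM (2.33 ± 0.24, adjusted p = 3.68e-05). Sema6d was lower (-1.02 ± 0.17, adjusted p = 0.00366), and Plxna1 (0.92 ± 0.16) and Sema5a (1.92 ± 0.32) were higher. Of the semaphorins, plexins and neuropilins, 4 of 30 tested genes rose and 2 fell, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.659). Negr1 (1.91 ± 0.14, adjusted p = 1.45e-06), Cadm2 (1.92 ± 0.23, adjusted p = 0.000181) and Cntnap2 (1.61 ± 0.20, adjusted p = 0.000273) were higher. Among contactins and related molecules 6 of 35 tested genes rose and 1 fell, with 10 higher and 5 lower adjusted over the list alone, a camera adjusted p of 0.0455, and 0.889 with an estimated correlation. Of the protocadherins, 3 of 11 tested genes rose and 0 fell (Pcdh9 0.88 ± 0.16, Pcdh7 1.21 ± 0.24, Pcdh19 1.5005 ± 0.36), with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.659). Of the cadherins 1 of 16 rose (Cdh4 1.09 ± 0.25), also over the list alone (0.887). Of the synaptic organizers, 3 of 40 tested genes rose and 1 fell, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.343). Tenm1 (1.65 ± 0.17, adjusted p = 4.31e-05), Lrrtm2 (1.00 ± 0.21) and Tenm3 (1.00 ± 0.24) were higher and the latrophilin gene Lphn3 was lower (-1.03 ± 0.17). Of the Eph receptors and ephrins 1 of 21 fell (Efnb2 -1.47 ± 0.28), with 3 higher and 4 lower adjusted over the list alone (0.659). In the Netrin and Slit list 1 of 22 rose (Neo1 0.72 ± 0.16), with 2 higher and 1 lower adjusted over the list alone (0.659). Unc5b was at -0.53 ± 0.72 (adjusted p = 0.758) and Unc5c at -0.19 ± 0.27 (0.772). Within set 2 Unc5c stood at 0.21, the opposite sign. Within set 2 the changes of Pcdh7 (0.106), Pcdh19 (0.125), Cdh4 (0.178), Lrrtm2 (0.0954), Tenm3 (0.202) and Neo1 (0.161) did not pass (adjusted p in brackets), and the list of contactins and related molecules was not called (camera adjusted p = 0.224).

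Some genes of synaptic vesicles and of transmission were higher. In the list of maturing neuron and synaptic vesicle genes, 5 of 27 tested genes rose and 0 fell, with 10 higher and 1 lower adjusted over the list alone. Among them were Syn1 (0.82 ± 0.16, adjusted p = 0.0104), Cplx2 (1.23 ± 0.24) and Syp (1.14 ± 0.24). The camera adjusted p of the list was 0.00840, or 0.889 with an estimated correlation, and within set 2 it was 0.151. Those 3 genes did not pass within set 2, where their adjusted p values were 0.0666, 0.0885 and 0.0994. Of the GABA and glycine receptors, 2 of 18 tested genes rose and 0 fell (Gabrb2 1.25 ± 0.22, Gabra4 1.37 ± 0.27), with 6 higher and 2 lower adjusted over the list alone, a camera adjusted p of 0.0106, and 0.955 with an estimated correlation. Of the immature neuron genes, 2 of 21 tested genes rose and 1 fell (Reln 1.36 ± 0.16, adjusted p = 0.000177; Gap43 0.70 ± 0.13; Neurod6 -2.09 ± 0.46), with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.942). The retinoic acid list had a median of -1.005 (within set 2 -0.72), with a camera adjusted p of 0.00904, and 0.419 with an estimated correlation. Of its 12 tested genes 5 had a positive change and 1 passed. That gene was Cyp26b1, a retinoic acid degrading enzyme (-1.79 ± 0.43, adjusted p = 0.0389). Adjusted over the list alone 0 higher and 2 lower passed. Single genes passed among glutamate receptors (with 4 higher and 1 lower adjusted over the list alone), potassium channels (Kcnd2 0.83 ± 0.19, with 2 higher and 0 lower) and neuropeptides (Sst -1.70 ± 0.39, with 0 higher and 1 lower), with camera adjusted p values of 0.513, 0.887 and 0.945. No Polycomb gene passed either way (0.802). Within set 2 the changes of Gabra4 (0.0823), Gap43 (0.0581), Neurod6 (0.0616), Cyp26b1 (0.137), Kcnd2 (0.154) and Sst (0.0643) did not pass (adjusted p in brackets).

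Vascular and meningeal markers did not pass in the driven group: the medians were 0.03 (camera adjusted p = 0.513) for endothelium, with 1 gene lower adjusted over the list alone, 0.75 (camera adjusted p = 0.887) for pericytes and 0.06 (camera adjusted p = 0.659) for meninges. Within set 2 these medians were -0.17, 1.17 and 0.73, and camera did not call the lists. The pericyte markers Abcc9 and Rgs5 ran from 0.326 to 15.0 and from 0.100 to 20.1 CPM over the driven libraries. Of the astrocyte markers 1 of 15 rose (Ptprz1 1.49 ± 0.30), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.887). The medians of the other marker lists were -0.42 (camera adjusted p = 0.945) for oligodendrocytes, -0.96 (camera adjusted p = 0.659) for microglia, -0.87 (camera adjusted p = 0.887) for ependyma, -0.07 (camera adjusted p = 0.945) for dividing cells. They were 0.02 (camera adjusted p = 0.887) for GABAergic, 0.29 (camera adjusted p = 0.837) for serotonergic, 0.52 (camera adjusted p = 0.926) for cholinergic and -0.30 (camera adjusted p = 0.343) for granule neurons. Adjusted over the list alone, 2 GABAergic, 1 serotonergic and 2 granule neuron genes were lower and 1 cholinergic gene was higher. The endothelial, meningeal and GABAergic medians turned to -0.09, -0.06 and -0.07 with library size as the only scaling. Th (-0.46) and Tfap2b, without a count in the driven group and at least 17.0-fold lower, did not pass, nor did Alas2 (-1.49) and Hbb-bs (-1.11). Of the stress genes 2 of 28 rose, Fosl2 (1.63 ± 0.29) and Klf6 (1.35 ± 0.24), also over the list alone (camera adjusted p = 0.887). Of the hypoxia genes it was 1 of 23 (Ero1l 0.87 ± 0.21, camera adjusted p = 0.845). The ribosomal protein list was lower (median -0.35, camera adjusted p = 0.00904, or 0.955 with an estimated correlation), but its median within set 2 was -0.02 (0.912). Histone and sex-linked genes had medians of -0.21 (camera adjusted p = 0.887) and -0.04 (camera adjusted p = 0.659). Median, mean and test did not share a sign for some lists that camera did not call, among them the rhombic lip, Eph, protocadherin, potassium channel, neuropeptide, Hox, endothelial and meningeal lists. Within set 2 the changes of Ptprz1 (0.114), Fosl2 (0.0595), Klf6 (0.0643) and Ero1l (0.0721) did not pass (adjusted p in brackets).

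In all, 271 genes passed in the second comparison, 191 higher and 80 lower, and camera called 5 of 37 lists, none of which held with an estimated correlation (fry called 1). Within set 2, 127 genes passed (79 higher, 48 lower), 111 of them among the 271, and all 271 kept their sign. There camera called 2 lists, the GABA and glycine receptors (adjusted p = 0.0107) and the retinoic acid pathway (0.0111), and with an estimated correlation neither held (0.854 and 0.654). The count of genes was 575 without driven replicate 1, and library size as the only scaling gave 105 higher and 94 lower. Of 63 named genes past the threshold, 43 stayed past it in every fit that left out 1 library. Without a driven library 5 to 10 no longer passed, without a reference 5 to 11, and without a Hoxa5tdTomato library 5 to 6. The number of lists was 1, 0 and 10 without driven replicates 1, 2 and 3, and 3 without any 1 of the set 1 references.

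The third comparison set Hoxa5tdTomato against the driven group, which lie in different sets, so that group and set cannot be told apart in it. Hoxa5 was at 2.11 ± 0.72, adjusted p = 0.0993 and did not pass. The largest increases in Hoxa5tdTomato included genes that had no count in the driven group: Slc22a8 was at least 411-fold higher, Aplnr at least 181-fold, Egfl7, an endothelial gene, at least 144-fold and Cmklr1 at least 121-fold. Abhd3, with 1 count in the driven group, had a ratio of 388 (95% interval 69.0 to 15412). The largest decreases were Esr1 (-4.73 ± 0.98, adjusted p = 0.0256), Nhlh1 (-3.90 ± 0.71, adjusted p = 0.0223), Lrr1 (-3.78 ± 0.97, adjusted p = 0.0449), Adamtsl1 (-3.20 ± 0.77, adjusted p = 0.0385) and Eya2 (-3.10 ± 0.77, adjusted p = 0.0426). Camera called the Hox genes of groups 5 to 13 (adjusted p = 5.22e-05), the endothelial (1.34e-08), pericyte (0.000690), meningeal (0.00247) and ribosomal protein lists (1.90e-12) as higher and the rhombic lip list (0.000227) as lower. With an estimated correlation none held, at 0.0557 for the Hox genes, 0.25 for the meningeal list and 0.314 for each of the others. The Hox list holds Hoxa5 itself and Hoxa7, which passed the filter only through Hoxa5tdTomato, and was not tested without them. On the difference of the within-set effects the ribosomal protein list had a median of 0.04 against 0.70 pooled and was not called (camera adjusted p = 0.493), nor were the pericyte and rhombic lip lists (0.0869 each). None of these 10 genes passed there: Slc22a8 (0.460), Aplnr (0.178), Egfl7 (0.373), Cmklr1 (0.417), Abhd3 (0.556), Esr1 (0.417), Nhlh1 (0.556), Lrr1 (0.367), Adamtsl1 (0.522), Eya2 (0.658), with the adjusted p in brackets. Nhlh1 was at -2.03 and Eya2 at -1.84.

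Here 493 genes passed, 135 higher and 358 lower, and 53 of them also differed between the references of the sets. The difference of the within-set effects removes the set only if the references of both sets are equivalent, which the labels do not settle, as their columns name creErt2 in set 1 and tdT in set 2. It had 0 genes past the threshold in edgeR, with 1181 at an unadjusted p under 0.05. The other tools were run on the pooled comparison, where DESeq2 gave 1484 and limma voom 384 genes. Without Hoxa5tdTomato replicates 1, 2 or 3 the pooled count was 0, 1 and 1, and 10 of the 10 named genes no longer passed. Without set 1 reference replicates 2 and 3 it was 297 and 281, without set 2 reference replicate 2 it was 260, and without driven replicates 1 and 3 it was 1157 and 242. Library size as the only scaling turned the balance to 116 higher and 32 lower, as it raised the median of all genes by 0.28. That shift was 0.16 in the first comparison and -0.12 in the second, and upper-quartile factors raised the median by 0.15 in the third.

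Of the genes changed in the same direction in both comparisons with the reference, the 10 first by the larger adjusted p are named. Higher in Hoxa5tdTomato and in the driven group (log2 values in that order) were Lmo3 (1.56 ± 0.21 and 2.62 ± 0.21), a LIM-domain cofactor gene, Cadm2 (1.799 ± 0.23 and 1.92 ± 0.23), Rnf152 (0.93 ± 0.12 and 1.40 ± 0.12), Negr1 (1.09 ± 0.14 and 1.91 ± 0.14), Tenm1 (1.25 ± 0.17 and 1.65 ± 0.17), Reln (1.12 ± 0.16 and 1.36 ± 0.16) and Brinp3 (1.44 ± 0.21 and 2.04 ± 0.21). Lower in both were Ncam2 (-2.00 ± 0.22 and -2.95 ± 0.23), Fat4 (-0.89 ± 0.13 and -1.35 ± 0.13), an atypical cadherin gene, and Wscd1 (-1.74 ± 0.26 and -2.25 ± 0.27). In total 68 genes changed alike, 50 higher and 18 lower, and 0 in opposite directions, where 2.32 would be shared if the calls were independent. The comparisons share the 6 references, and in 50 simulations of unchanged groups against shared references 0 genes were called in both. Those simulations held no changed genes and no difference between the sets. They therefore cannot show how far shared references raise the overlap between lists of changed genes. Within the sets, which share no library, 26 genes changed alike (16 higher, 10 lower; 0.358 if independent), 24 of them among the 68. Among these were Nrp2 (1.73 and 2.04), Sema6d (-0.95 and -0.95) and Gabrb2 (1.30 and 1.40), with the log2 values within set 1 and set 2; these 3 were picked after their values were seen. Of the 82 genes called within set 1, 73 (89.0%) had the same sign within set 2, 53 of them at an unadjusted p under 0.05, and of the 127 called within set 2, 118 (92.9%) had the same sign within set 1, 77 of them at an unadjusted p under 0.05. Among all tested genes the share was 54.7%.

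Across the genes above 5 CPM, which are not independent replicates, the fold changes of both comparisons correlated with r = 0.198 pooled and r = 0.251 within the sets. The simulated unchanged groups, which held no difference between the sets, gave r = 0.330 from the shared references alone. The pooled covariance was 0.0703, against 0.0551 in the simulations (SD 0.00243), a difference of 0.0152, while over all tested genes it was 0.1698, against 0.198 in the simulations. Within the sets the covariance above 5 CPM was 0.0861. Over all tested genes r was 0.145 pooled, against 0.313 in the simulations, and 0.0866 within the sets. The number of genes changed alike was 21, 20 and 24 without Hoxa5tdTomato replicates 1, 2 and 3, 43 to 45 without set 1 reference replicates 1, 2 or 3 or set 2 reference replicates 1 or 3, and 139 without driven replicate 3.

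**Figure D4:**
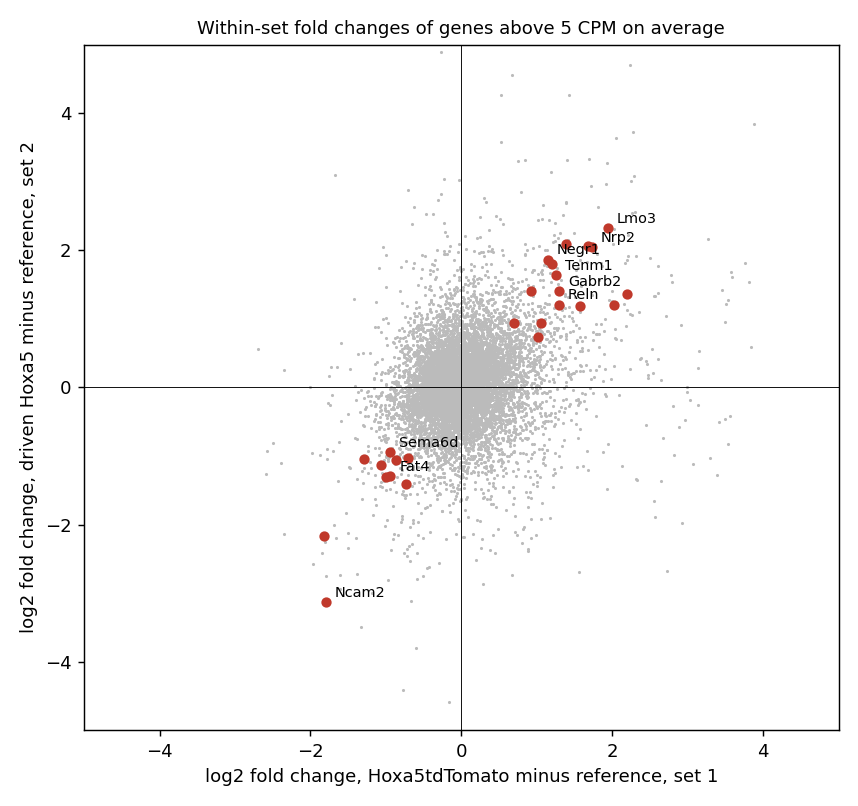
Log2 fold change of each gene above 5 CPM on average in Hoxa5tdTomato against the set 1 references (x axis) and in the driven group against the set 2 references (y axis); each grey point is 1 gene, 10900 in all, and 8 points lie outside the axes. Red points mark the 26 genes past the threshold in both within-set comparisons, of which 16 lie in the upper right and 10 in the lower left corner, with some of them named.

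On mm10, the genes given first in these comparisons are protein-coding genes at the following positions: Hoxa4 (Entrez 15401, chromosome 6, 52189682 to 52191703), Hoxa5 (Entrez 15402, chromosome 6, 52201754 to 52204587), Hoxa7 (Entrez 15404, chromosome 6, 52215623 to 52218573), Hoxb5 (Entrez 15413, chromosome 11, 96303512 to 96306121), Hoxc4 (Entrez 15423, chromosome 15, 103018097 to 103036856), Ncam2 (Entrez 17968, chromosome 16, 81200697 to 81624290), Cadm2 (Entrez 239857, chromosome 16, 66655416 to 67620917), Negr1 (Entrez 320840, chromosome 3, 156561790 to 157316464), Nrp1 (Entrez 18186, chromosome 8, 128358591 to 128505476), Nrp2 (Entrez 18187, chromosome 1, 62703317 to 62818692), Reln (Entrez 19699, chromosome 5, 21884454 to 22344705), Tenm1 (Entrez 23963, chromosome X, 42527866 to 43429168), Calb1 (Entrez 12307, chromosome 4, 15881264 to 15906709), Lhx2 (Entrez 16870, chromosome 2, 38339271 to 38369737) and Lmo3 (Entrez 109593, chromosome 6, 138362918 to 138582206). Counts cover whole gene models, and the table does not part exons or transcripts.

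The references of the sets, which carry the same label, were compared as a check of the set. In edgeR 197 genes differed, 105 higher and 92 lower in set 1. The ribosomal protein list was higher in set 1, with 20 of 77 genes past the threshold, a median of 0.68 and a camera adjusted p of 1.19e-26, or 0.0149 with an estimated correlation. The rhombic lip list (median -0.51, camera adjusted p = 0.00393, or 0.663 with an estimated correlation) and the maturing neuron list (median -0.26, 0.0172, or 0.646) were lower in set 1. Ribosomal protein genes took 0.719% to 0.896% of the counts in set 1 and 0.427% to 0.489% in set 2.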

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

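The tests chosen only after the results were seen were the splits of the libraries, both tests of the purity of the neurons, the test of the library set for the vascular genes, the test of the driven transcript, and the test of preparation or sequencing.

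Among the 6 references, 139 values were tested for a library far from the others, and 5 were found, where chance gives about 5%. The lowest library stood apart for Brinp3 in set 2 replicate 3 at 18.6 CPM (others 29.5 to 38.0), Grm5 in set 2 replicate 3 at 44.0 CPM (others 106 to 123), Hoxa4 in set 1 replicate 1 at 4.44 CPM (others 12.7 to 22.5), Pcdh19 in set 2 replicate 3 at 41.4 CPM (others 81.5 to 117) and Xist in set 2 replicate 2 at 9.56 CPM (others 1570.1 to 4636.6). Set 2 reference replicate 2 was male by its sex-linked genes, with Ddx3y, a gene of the Y chromosome, at 41.8 CPM.

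The effects of the sets, Hoxa5tdTomato against its references and driven against its references, differed for 6 lists by camera on the difference itself. The adjusted p values were 0.0234 for the Hox genes of groups 1 to 4 and 8.09e-06 for groups 5 to 13, 0.0343 for retinoic acid genes, 0.0306 for GABAergic markers, 9.99e-08 for endothelial and 0.0266 for meningeal markers. The medians of the differences were 0.76, 3.55, 0.67, 2.95, 3.14 and 2.09. With an estimated correlation none held, at adjusted p values of 0.354, 0.0828 and 0.295 for the first 3 lists and 0.295 for each of the others. The list of groups 5 to 13 holds Hoxa5, through which the Hoxa5tdTomato neurons were labelled, and Hoxa7, which passed the filter only through that group.

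Vascular and meningeal marker lists had higher medians in Hoxa5tdTomato, and RNA of vascular cells in the sorted material is a candidate explanation. Over all genes 1 of 14 endothelial, 2 of 10 pericyte and 0 of 8 meningeal markers passed, and 12, 7 and 4 adjusted over the list alone. The camera calls of these lists did not hold with an estimated correlation (adjusted p = 0.150 each). On a separate list of 30 abundant endothelial and mural genes, 29 were tested, with a median within set 1 of 2.56 (quartiles 1.93 to 3.39), 28 positive and 20 higher in all 3 libraries than in the set 1 references, where chance gives 5% for a single gene and these genes are not independent. Of these genes 7 reached 5 CPM in the references, and the most abundant were at 165 against 113 CPM (Bsg, 0.54), 74.7 against 19.9 CPM (Sparc, 1.91) and 65.2 against 65.4 CPM (Vim, -0.01). The library set is argued against by the endothelial median of 3.36 within set 1 (quartiles 2.89 to 3.62). In replicates 2 and 3, low-level vascular markers moved 2.61 ± 0.46 and 3.48 ± 0.56 further than low-level markers of microglia, oligodendrocytes, ependyma and erythroid cells. An equal rise of those other types is argued against there. The vascular lists were already seen to be high, and meningeal and astrocyte markers were left out of this test. It therefore cannot decide on a lower purity in general, which stays open. In replicate 1 the difference of 0.90 ± 0.56 leaves an equal rise open. These errors were taken over marker genes within 1 library, which are not independent, so they do not measure the spread between libraries. The FACS gate on labelled cells would remove vascular cells without the label, so labelled vascular cells, cells that adhered to neurons, free RNA and a biological difference between the neurons stay open.

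Hoxa5 did not pass in the driven group. Wrongly labelled references are argued against by a score on 82 genes of the first comparison within set 1. All 3 driven libraries scored above the set 2 references, with a gap of 0.287 (SD of the references 0.229), which rests on 3 libraries against 3. The score did not follow Hoxa5. Driven replicate 3, with Hoxa5 at 82.0 CPM, scored lowest (0.538), while replicates 1 and 2, at 9.73 and 16.8 CPM, scored 0.860 and 0.796. A driven transcript outside the counted gene model cannot be told apart from a low level, as only 1 driven library lay above the highest set 2 reference and the table holds no reads. The level of the driven allele in these neurons stays open as a biological explanation and was not tested.

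Ribosomal protein genes were higher in the set 1 references, and a bias by gene length between the sets is a candidate explanation. Other genes matched on length and level differed by a median of 0.56 (95% bootstrap interval 0.35 to 0.73), which is 81.7% of the ribosomal median of 0.68, but 56 of the 77 ribosomal genes lay above their own matches, so length is not shown to be the whole cause. The interval was drawn over genes, which are not independent, so it does not measure the spread between libraries. Without the ribosomal genes the median difference was 0.85 for genes under 0.5 kb, 0.51 up to 1 kb, 0.16 up to 2 kb, and -0.01, -0.07 and -0.06 for the longer classes. The percent of counts in ribosomal protein genes did not overlap between the sets, with a gap of 0.230, but preparation and sequencing cannot be told apart, since no label separates them.

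Of 84 splits of the 9 libraries of the first comparison, 2 gave as many genes as the real 255. The other, with 621 genes, put the 3 set 2 references together and follows the set, within which 82 genes passed. These splits ignore the set, so they cannot tell whether chance within a set gave the count. For the second comparison 2 of 84 splits gave as many as the real 271, and the other, with 404 genes, put the 3 set 1 references together, against 127 within set 2. For the lists of the first comparison, 3 of 84 splits gave as many as the real 14 (highest other 14). The lists were not split within the sets, so chance within a set was not tested. For the lists of the second comparison, 16 of 84 gave as many as the real 5 (highest other 11), so that chance is not excluded there. For the genes changed alike in both, 1 of 100 splits, the real one, gave as many as 68, and the highest other gave 0. Drawn over all libraries, those splits mixed the groups, so they do not show how far shared references raise the overlap. The 10 splits of 3 against 3 are too few for a share under 0.05: the real and highest other counts were 493 and 0 in the third comparison, 82 and 0 within set 1, 127 and 45 within set 2, and 197 and 0 between the references, each with 1 split as large as the real one, which was the real one itself.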

How the results depend on the processing

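Alternatives chosen only after the data were seen were the fits within the sets, the block by column numbers and the thinned counts. The count of 255 genes in the first comparison was 601 with DESeq2, 1742 with limma voom, 735 with only the groups compared, 43 at an adjusted p of 0.01 and 19 at a minimum fold of 1.5. Within set 1 it was 82, or 72 with a block, 81 on thinned counts and 362 without driven replicate 3. The 271 of the second were 831 with DESeq2, 166 with only the groups compared, 86 at 0.01 and 72 at the minimum fold, and within set 2 127, 77 with a block, 130 on thinned counts and 363 without driven replicate 3. The 493 of the third were 163 with upper-quartile factors, 148 with library size alone, 1484 with DESeq2, 142 with only the groups compared, 1 at 0.01, 1 at the minimum fold and 114 with a block. As a difference of within-set effects they were 0 in edgeR (1181 at an unadjusted p under 0.05), also 0 without driven replicate 3, with a block and on thinned counts. The 68 genes changed alike were 137 with DESeq2, 152 with voom, 18 at 0.01 and 6 at the minimum fold. Within the sets they were 26, with a block 26, on thinned counts 28 and without driven replicate 3 113. The 14 lists of the first comparison were 1 with an estimated correlation. The 5 of the second were 0 with an estimated correlation, 1 with fry, 2 within set 2, 1 with a block there, 2 on thinned counts and 8 without driven replicate 3. In the first comparison fry gave an adjusted p of 7.73e-05 for the Hox genes of groups 5 to 13. It gave 0.00732 for each of the Wnt, immature neuron, endothelial and pericyte lists. Among the lists that fry did not call were the rhombic lip (0.0678) and ribosomal protein lists (0.0612).

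Leaving out 1 library gave 35 to 728, 190 to 575 and 0 to 1157 genes in the 3 comparisons, 20 to 139 changed alike, and 8 to 15 and 0 to 10 lists. Hoxa5 in Hoxa5tdTomato stayed at 3.11 to 3.92 without 1 library. It missed the threshold within set 1 (3.53, adjusted p = 0.0698; but 0.00279 there without driven replicate 3, 0.00467 with a block and 0.0499 on thinned counts) and without Hoxa5tdTomato replicate 2 (3.11, adjusted p = 0.0693), where the adjusted p over all alternatives ran from 2.79e-06 to 0.0698, and DESeq2 gave no adjusted p. In the driven group Hoxa5 ran from -0.10 (without replicate 3) to 1.797 without 1 library, and within set 2 without replicate 3 it was -0.17. Its adjusted p ran from 0.0890 to 0.956. In the driven group Unc5b stood at -1.17 without replicate 2 but turned to 0.0445 without replicate 3 and to 0.0402 within set 2 without replicate 3, and Unc5c turned to 0.21 within set 2, 0.39 there without replicate 3, 0.26 with a block and 0.15 on thinned counts. Stricter thresholds lower the counts by construction; for the other differences the cause was not tested.

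Of 146 results for named genes, 142 kept direction and side of the threshold with RLE factors, 135 with upper-quartile factors, 130 with library size alone, 144 with DESeq2, 127 with voom, 119 with a block and 72 within the sets, where 73 no longer passed. Replicates that shared a number showed little common variation (r = -0.03 to 0.05 over the pairs), and r ran from -0.0993 to 0.0945 where the numbers differed. With so few pairs of deviations from group means, this does not settle whether the numbers pair the libraries. The planned block by label numbers was not run. Depth differs with the set, and thinning to the shallowest library left the pooled counts at 260.0, 297 and 417.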

Other observations

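Among the first 10 genes changed alike within both sets were 3 whose values are not given above. Spock1, which encodes an extracellular matrix proteoglycan of the brain, was higher in Hoxa5tdTomato within set 1 and in the driven group within set 2, in that order: Spock1 (1.20 ± 0.14, adjusted p = 0.000951, and 1.799 ± 0.14, adjusted p = 8.94e-06). St18, a zinc finger transcription factor gene, was higher in both, St18 (2.20 ± 0.23, adjusted p = 0.000469, and 1.36 ± 0.22, adjusted p = 0.00632), and Aff2, which encodes a nuclear protein of the AF4 family, was lower in both, Aff2 (-1.30 ± 0.15, adjusted p = 0.000951, and -1.05 ± 0.15, adjusted p = 0.00257). Each n was 3 against 3. The tests within the sets were chosen after the data were seen.

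Robo1, a Slit receptor gene, differed between the references of the sets, at 35.5 ± 4.30 CPM in set 1 and 158 ± 41.4 CPM in set 2 (-2.16 ± 0.29, adjusted p = 0.0023, n = 3 against 3). It was picked after its values were seen. Ddx3y, on the Y chromosome, was at 0 to 0.0899 CPM in driven replicates 1 and 2 and set 2 reference replicate 3, and at 5.43 to 47.9 CPM in the other libraries. In the set 1 references, set 2 reference replicate 1 and Hoxa5tdTomato replicates 2 and 3, Xist at 1570.1 to 4194.2 CPM stood together with Ddx3y at 5.43 to 26.1 CPM.

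The median correlation of a library with the other 11 was lowest for driven replicate 3, at r = 0.865, against 0.900 to 0.922 for the others. Its TMM factor was 0.852, the lowest, and its voom quality weight was 0.142, against 0.455 to 2.55 for the others.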
